A study of Mus musculus with 24 samples.

How the data were processed

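The series profiled mouse E14 embryonic stem cells, a line that keeps the ability to form all tissues of the embryo, after the introduction of TET3, an enzyme that oxidises methylated cytosine in DNA. Per the labels' protocols, cells were grown in serum with LIF and sorted by flow cytometry for green fluorescent protein, and the control is green fluorescent protein. Of the 24 libraries, 9 hold RNA (3 control, 3 TET3 and 3 TET3-trunc), 6 hold ATAC-seq (3 control and 3 TET3), which reads out accessible DNA, and 9 hold ChIP-seq with an antibody to TET3 (2 TET3, 3 TET3-CXXC, 3 TET3-trunc and 1 input). The names of the constructs are those of the labels, which do not say which parts of the protein TET3-CXXC and TET3-trunc hold or lack. Groups and replicate numbers were taken from the sample titles. The labels do not state whether replicates are separate cultures, so p-values measure only the spread between these samples, which may be technical.

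Per the submitters' processing notes, reads were trimmed with Trim Galore 0.4.2 and aligned with TopHat2 2.0.12 or Bowtie2 2.2.5 to GRCm38. RNA libraries were made from total RNA after removal of ribosomal RNA with a stranded kit, per the labels' protocols. The authors deposited all values as log2 RPM, that is, the log2 of reads per 1e6 reads, per gene for RNA and per tile of 500 bp for ATAC and ChIP. In these deposited log2 values a feature without reads is written as if it had 0.9 reads. This sets the lowest value of each library, from which the reads per library and the reads behind each value were recovered: the recovered reads of values that are printed precisely enough came out whole within 0.01 reads. The tile tables used here hold only part of the genome. The ATAC table covers chromosomes 1 and 2 and chromosome 3 up to position 146702000 (1048575 tiles), and the ChIP table covers chromosome 1 and chromosome 2 up to position 142049500 (675043 tiles, with 1 incomplete line left out). Other regions were not analysed here in ATAC and ChIP, among them the Tet3 gene on chromosome 6. RPM is relative to the reads of each library, so a change in the total RNA of a cell cannot be seen in these values.

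Recovered depth was 28.3 to 32.0 M reads (M, 1e6) in the RNA control libraries, 42.1 to 134.3 M in RNA TET3 and 96.2 to 177.8 M in RNA TET3-trunc. The deeper groups therefore carry less counting error, and low genes of the control are measured least precisely. ATAC libraries had 25.6 to 44.8 M reads and ChIP libraries 27.1 to 40.9 M. Correlations of log2 RPM between replicates were 0.965 to 0.989 for RNA genes, 0.39 to 0.587 for ATAC tiles and 0.265 to 0.598 for ChIP tiles, so a 500 bp tile is measured far less precisely than a gene. Some libraries lay closer to another group than to their own. RNA control replicate 1 had r = 0.992 with TET3-trunc replicate 3, but 0.972 and 0.965 with the other controls. RNA TET3 replicate 3 had 0.985 with TET3-trunc replicate 3, but 0.974 and 0.976 with TET3 replicates 1 and 2. The 2 ChIP TET3 libraries had 0.265 with each other, while TET3 replicate 1 had 0.446 with TET3-CXXC replicate 2. The ChIP table holds 15.5% to 16.3% of the RPM total of the input and TET3-CXXC libraries, and 22.9% to 23.7% of that of the TET3 and TET3-trunc libraries. Among tested tiles, the median log2 difference from input was 0.91 for TET3, 0.80 for TET3-trunc and 0.14 for TET3-CXXC. Over all tiles with no filter it was 0.0124, -0.0706 and -0.598, so its size depends on the filter.

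Differences were tested with limma 3.58.1 in R 4.3.3 on the deposited log2 RPM, with an intensity trend and robust variance moderation, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. The RNA fit held all 9 RNA libraries and the 12650 genes with at least 1 RPM in at least 3 libraries. The ATAC fit held 30333 tiles with at least 0.5 RPM in at least 3 of the 6 libraries, and the ChIP fit 105513 tiles with at least 0.5 RPM in at least 2 of the 9 libraries. The input is 1 library, so its spread was assumed to be that of the other groups. No pseudocount was added in these fits. Fold changes of features near 0 reads depend on the value written for 0 reads.

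Gene lists were fixed before the data were examined. Of 925 entries 903 matched a gene of the table and 762 were tested, in 31 lists with at least 3 tested members. Each list was tested with camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry, and p-values were adjusted over the lists. The genes named in the text were also chosen by a rule fixed before the data were examined: Tet3 and 8 related genes, then the 10 largest rises and the 10 largest falls among called genes whose libraries did not overlap between the groups, and up to 4 called members of each list, or 2 given as values where none was called. Genes known only by a clone or predicted-gene name were left out of the leading 10. Leading genes had to reach 1 RPM on average in the higher group. Named tiles were up to 5 rises and 5 falls of largest log2 change per comparison, the strongest of each run of called tiles within 1 kb, the 5 bound tiles of highest enrichment per construct, and tiles at the starts of named genes.

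A tile was taken as bound by a construct when each of its libraries lay at least 1 log2 unit above the input and their mean reached 0.5 RPM. Bound thus means enriched over the input, since no ChIP of control cells is among the libraries. For ATAC at bound tiles and RNA at bound promoters, bound and unbound features were matched on their mean level in bins of 0.1 log2, and 1 value per library was compared with a two-sided exact permutation test. With 3 libraries against 3 its smallest p is 0.1. Gene starts were taken from the coordinates in the RNA table. For the relation between the TET3 and TET3-trunc effects, which share the control libraries, 100 sets of unchanged groups were simulated. They were drawn from the deviations of all RNA libraries, and in each set 3 simulated libraries were shared as control. The real control libraries were not held fixed.

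The tests were run on simulated data in which 200 features were changed. In the simulated RNA comparison of TET3 with control, over 12650 genes, 61% of genes changed by 1 log2 unit and 95% of those changed by 2 were called. In the simulated ATAC comparison, over 30333 tiles, 0% of tiles changed by 1 log2 unit, 30.3% of those changed by 2 and 56.1% of those changed by 4 were called. In the simulated ChIP comparison of TET3-CXXC with TET3-trunc, over 105513 tiles, the shares were 0%, 6.06% and 50%.

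The alternatives were other pseudocounts, filters and scalings, voom on the recovered reads, no intensity trend, a fit of the compared groups alone, a replicate block, each library left out, other thresholds for bound tiles and other ways of matching. Thinned reads, array weights, pairs of libraries left out together and a median shift of the bound tiles were added after seeing the data. Figures were drawn with matplotlib 3.10.9. Base composition was not analysed here.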

Results

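The data describe how mouse E14 embryonic stem cells that carry TET3, or a construct named TET3-trunc, differ from control cells with green fluorescent protein. RNA was measured in 3 libraries per group, accessible chromatin by ATAC-seq in 3 control and 3 TET3 libraries, and binding by ChIP-seq in 2 TET3, 3 TET3-CXXC and 3 TET3-trunc libraries beside 1 input. The title of the series asks about a role of TET3 in open chromatin and transcription apart from its catalytic activity. RNA depth was 28.3 to 32.0 M reads in control, 42.1 to 134.3 M in TET3 and 96.2 to 177.8 M in TET3-trunc (M, 1e6).

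The Tet3 transcript (ENSMUSG00000034832, GRCm38 chromosome 6, 83362373 to 83441678) was at 5.84 ± 1.35 RPM (SD, n = 3) in control, 411 ± 110 RPM in TET3 and 110 ± 42.7 RPM in TET3-trunc. This was a 69.7-fold rise in TET3 (limma adjusted p = 4.88e-06), and the log2 rise in TET3-trunc was 4.17 (limma adjusted p = 0.000308). Every library of both constructs lay above every control library. Of the 25 tested genes of DNA methylation and demethylation, Apobec1, a cytidine deaminase gene, fell from 3.56 ± 0.809 to 1.46 ± 0.657 RPM in TET3 (limma adjusted p = 0.0492), and 3, with Tet3 among them, were higher and 2 lower when adjusted over the list alone. The other genes given here did not pass the test in TET3. Tet1, the main dioxygenase of embryonic stem cells, was at 443 ± 122 RPM in control and 274 ± 47.7 RPM in TET3 (limma adjusted p = 0.135). Tet2 was at 154 ± 57.1 and 135 ± 21.5 RPM (limma adjusted p = 0.76). The log2 changes of Dnmt1, Dnmt3a, Dnmt3b, Dnmt3l, Uhrf1 and Tdg were -0.31, -0.28, -0.23, 0.76, 0.15 and -0.31, with limma adjusted p from 0.107 to 0.581.

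The first comparison asked which transcripts differ between TET3 and control cells. In TET3 cells, 12 of 23 tested genes of the 2-cell-like state rose, and 11 of 13 transcripts encoded by mitochondrial DNA fell. Pramel7, a gene linked to naive pluripotency (chromosome 2, 87489087 to 87497093), went from 1.43 ± 0.808 to 10.9 ± 2.51 RPM (SD, n = 3), an 8.34-fold rise (limma adjusted p = 0.0089). Its neighbour Pramel6 rose 5.66-fold and Tcstv1, a gene of the 2-cell stage, rose 5.85-fold. At the other end mt-Atp8, a subunit of mitochondrial ATP synthase, went from 287 ± 99.9 to 39.5 ± 23.2 RPM and fell by 2.94 on the log2 scale (limma adjusted p = 0.0089).

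In all, 1187 of 12650 genes passed the test, 672 of them higher and 515 lower in TET3, and 264 and 256 of these changed at least 2-fold. Which direction held more genes depended on the processing. The split was 620 higher and 612 lower after a median shift, 636 and 727 after quantile normalization, and 1477 and 1666 without TET3 replicate 3. With no filter it was 1774 and 7900. Genes without reads then enter at the lowest log2 RPM of each library, -5.15 to -4.98 in control and -7.22 to -5.55 in TET3. Such genes read as lower in TET3 through depth alone. The other leading rises were Pkd1l2 (7.89-fold), the transporter Abcb5 (6.62-fold), Xlr3c (6.4-fold), Spink10 (6.26-fold), Pramef17 (5.65-fold), the glucose transporter Slc5a1 (5.23-fold) and Ushbp1 (5.21-fold). Mean levels in TET3 were low for Pkd1l2 (1.7 RPM), Spink10 (1.27 RPM) and Ushbp1 (1.78 RPM). The leading falls held 5 mitochondrial transcripts, mt-Atp8, mt-Nd2, mt-Nd4l, mt-Atp6 and mt-Cytb. Outside mitochondrial DNA they were Ankrd34a, Nexn, Hapln4, Gstm3 and Sfrp2, an inhibitor of Wnt signalling that went from 8.21 ± 3.75 to 1.56 ± 0.821 RPM. Members of the Pramel, Zscan4, Xlr and histone families resemble each other, so their reads can be shared between copies.

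Genes of the 2-cell-like state, the pattern of transcripts of the embryo at the onset of its own transcription, were higher in TET3 for all 23 tested members. Of these 12 rose, and 19 passed when adjusted over the list alone. Zscan4f, which marks this state in stem cell cultures, went from 69.9 ± 54.9 to 248 ± 53.6 RPM (limma adjusted p = 0.0269), Zscan4d from 32.6 ± 25.6 to 116 ± 26.4 RPM and Gm8300 from 24.4 ± 17.4 to 100 ± 52.7 RPM. The median log2 change of the list was 1.73 and camera gave adjusted p = 1.28e-09 with the preset correlation, but adjusted p = 0.964 with an estimated correlation. The control libraries spread widely: relative to the mean of the 9 libraries, the list mean was 0.22 in control replicate 1, -0.98 in control replicate 2 and -1.85 in control replicate 3, and 0.32 to 1.38 in TET3.

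Germline genes that are silenced by DNA methylation in most cells rose for 10 of 29 tested members, with 14 higher and 2 lower when adjusted over the list alone. Among them were D1Pas1, a helicase gene of male germ cells (4.85 ± 0.618 to 14.2 ± 4.91 RPM), Stk31 (2.7-fold), Hormad1, which acts on meiotic chromosomes (2.49-fold), and Rpl10l (2.21-fold). The list as a whole gave camera adjusted p = 0.0554. Naive and core pluripotency genes went both ways: of 26 members Fbxo15 (2.31-fold) and Dppa5a (1.75-fold) rose and Utf1 and Klf2 fell, with 6 higher and 4 lower when adjusted over the list alone. Of 18 genes of the formative and primed epiblast, Fgf15 and Pou3f1 fell, 4 passed when adjusted over the list alone, and camera gave adjusted p = 0.0265 (adjusted p = 0.964 with an estimated correlation). Of 28 imprinted genes 3 fell: Phlda2, from 14.9 ± 3.2 to 3.5 ± 2 RPM, Mest and Cdkn1c, an inhibitor of the cell cycle.

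All 13 tested transcripts of mitochondrial DNA were lower in TET3. Of these 11 fell, and all 13 passed when adjusted over the list alone. The median log2 change was -2.11 (camera adjusted p = 5.22e-12, and adjusted p = 0.964 with an estimated correlation). The share of gene reads from mitochondrial DNA was 1.29%, 2.18% and 2.13% in the control libraries and 0.491%, 0.454% and 1.15% in TET3 replicates 1, 2 and 3. The genes mt-Atp8 and mt-Atp6 overlap, so reads of the shared stretch cannot be told apart. Nuclear genes of oxidative phosphorylation went the other way: of 32 members 6 rose, among them Ndufa2 (2.07-fold) and Cox7c (1.83-fold), and 14 passed when adjusted over the list alone (camera adjusted p = 1.12e-05, and adjusted p = 0.964 with an estimated correlation). TET3 replicates 1 and 2 carried this rise, with list means of 0.17 and 0.37, while TET3 replicate 3 (-0.03) lay just above control replicate 1 (-0.05). Of 47 ribosomal protein genes 4 rose, among them Rps14 (2.14-fold) and Rps3 (2.1-fold), and 2 fell, including Rpl10, with 21 higher and 3 lower when adjusted over the list alone (camera adjusted p = 8.55e-05, and adjusted p = 0.964 with an estimated correlation). The ribosomal list means of the groups overlapped, since TET3 replicate 3 (-0.10) lay below control replicate 1 (0.02) and only TET3 replicates 1 and 2 (0.17 and 0.34) lay above it.

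Replication-dependent histone genes, which supply histones in S phase, fell for 8 of 33 members, and 11 passed when adjusted over the list alone. Hist1h3d went from 45.1 ± 8.16 to 23.4 ± 1.55 RPM and Hist2h3c2 from 68.3 ± 6.37 to 39.1 ± 4.17 RPM (camera adjusted p = 8.55e-05 for the list, and adjusted p = 0.964 with an estimated correlation). Among 53 genes of chromatin remodelling 10 fell and 1 rose, with 15 lower and 1 higher when adjusted over the list alone. Those that fell included Chd7 (82.8 ± 23.2 to 36.5 ± 6.46 RPM), Mta1, Smarcd1 and Arid1b, subunits or helicases of remodelling complexes (camera adjusted p = 1.21e-04, and adjusted p = 0.964 with an estimated correlation). Of 36 genes of RNA polymerase II transcription, the Mediator subunits Med1 and Med14 and the elongation cofactor Brd4 fell, and the list did not pass (camera adjusted p = 0.835). Of 26 genes of the integrated stress response only Slc3a2 fell, 0 passed when adjusted over the list alone, and 22 had a lower value (camera adjusted p = 0.0139, and adjusted p = 0.964 with an estimated correlation). List means of the groups overlapped here and for the formative and primed epiblast.

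Markers of other cell types changed in small numbers. Among 16 fibroblast and feeder markers Vim rose from 77.6 ± 14.2 to 178 ± 29.8 RPM and Twist1 rose 2.36-fold, while the list did not pass (camera adjusted p = 0.973). Among 11 neural genes Neurod1 and Elavl3 fell and Stmn2 rose. Of 12 primitive endoderm genes Sparc rose 1.48-fold. None of 13 trophoblast and 8 mesoderm genes passed. The trophoblast keratin Krt8 was at 43.6 ± 25.9 RPM in control and 124 ± 44.7 RPM in TET3 (limma adjusted p = 0.0816).

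Of the 1187 called genes, 1155 had no overlap between the libraries of the 2 groups. Among all tested genes 30.3% had none, where chance gives 10%. The number of calls rested on few libraries: it was 2 without TET3 replicate 1, 1 without TET3 replicate 2, 62 without control replicate 2, 8 without control replicate 3, 1809 without control replicate 1 and 3143 without TET3 replicate 3, and voom on the recovered reads gave 265. Of the 31 lists 0 passed fry in one direction, and the lowest adjusted p was 0.0843, for mitochondrial transcripts. TET3 replicates 1 and 2 lay farthest from the controls on the first principal component (54.3 and 43.3, with 11.3 for TET3 replicate 3).

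**Figure D1:**
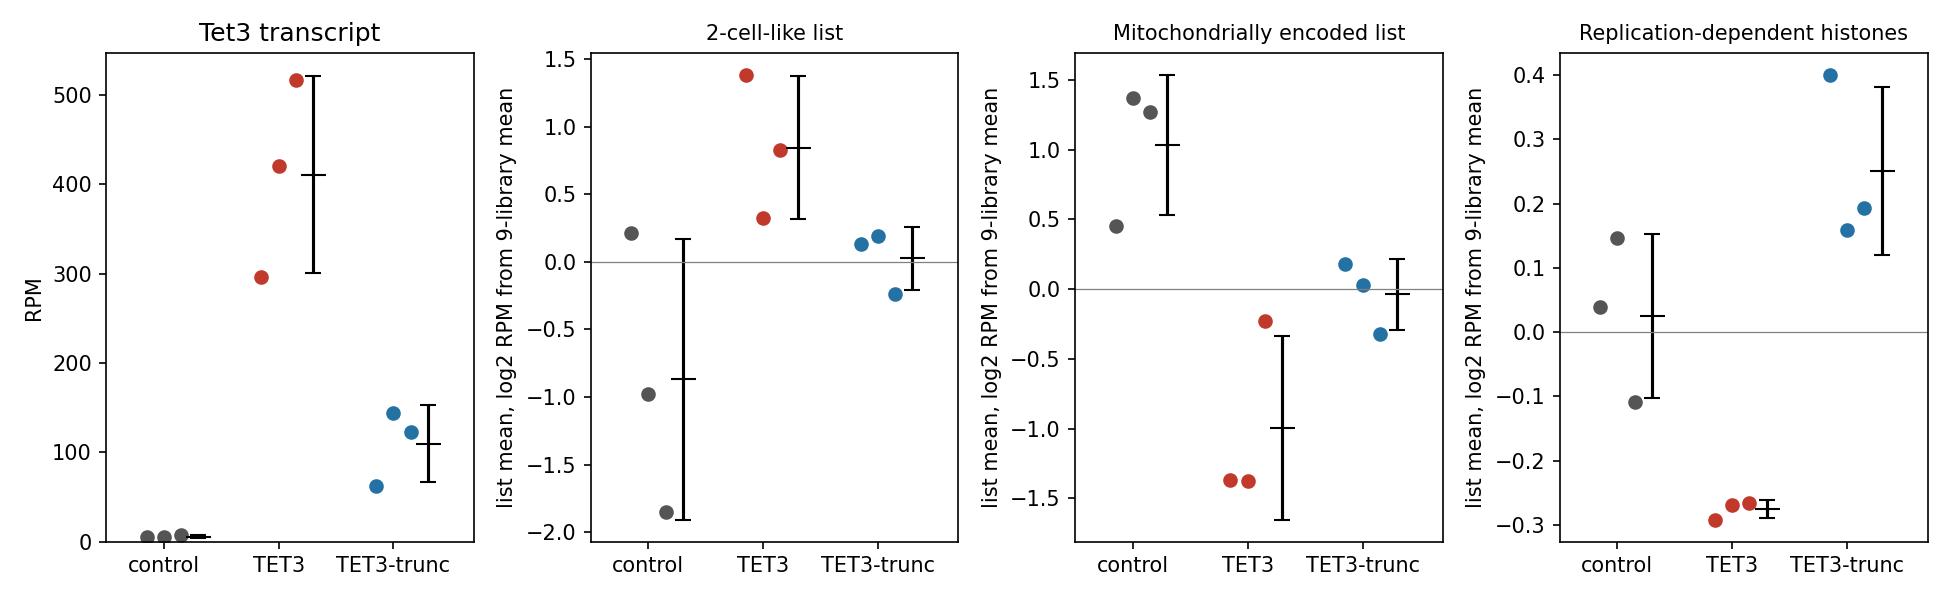
Points are single RNA libraries and black bars the mean ± SD of 3 libraries, for the Tet3 transcript in RPM and for the mean log2 RPM of 3 gene lists relative to the mean of the 9 libraries. TET3 libraries lie above all control libraries for the 2-cell-like list (0.32 to 1.38) and below them for mitochondrial transcripts (-1.38 to -0.23).

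The second comparison asked which of these changes occur with TET3-trunc. Against control only Tet3 itself passed the test, and 829 of 12650 genes had an unadjusted p below the threshold. The gene groups that led the TET3 comparison had smaller median changes here. The 2-cell-like list had a median log2 change of 1.01 with 22 of 23 members higher, and 0 passed when adjusted over the list alone. Zscan4f was at 118 ± 22.9 RPM (limma adjusted p = 0.738 against control). The mitochondrial list had a median of -1.23 with 13 of 13 members lower, and 9 passed when adjusted over the list alone. With mt-Atp8 at 91.5 ± 16.2 RPM, these cells lay between control and TET3. Replication-dependent histone genes were higher for 29 of 33 members, with a median of 0.24. Camera with the preset correlation called 14 of the 31 lists, among them the 2-cell-like (adjusted p = 2.06e-06), mitochondrial (adjusted p = 7.12e-18), histone (adjusted p = 1.56e-04), trophoblast (adjusted p = 0.00499) and splicing (adjusted p = 6.11e-09) lists. With an estimated correlation 0 lists passed, and the lowest adjusted p was 0.0851, for nuclear noncoding RNAs. Fry also passed 0 lists in one direction, with a lowest adjusted p of 0.249. List means of the TET3-trunc and control libraries overlapped for the 2-cell-like, trophoblast and splicing lists.

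**Figure D2:**
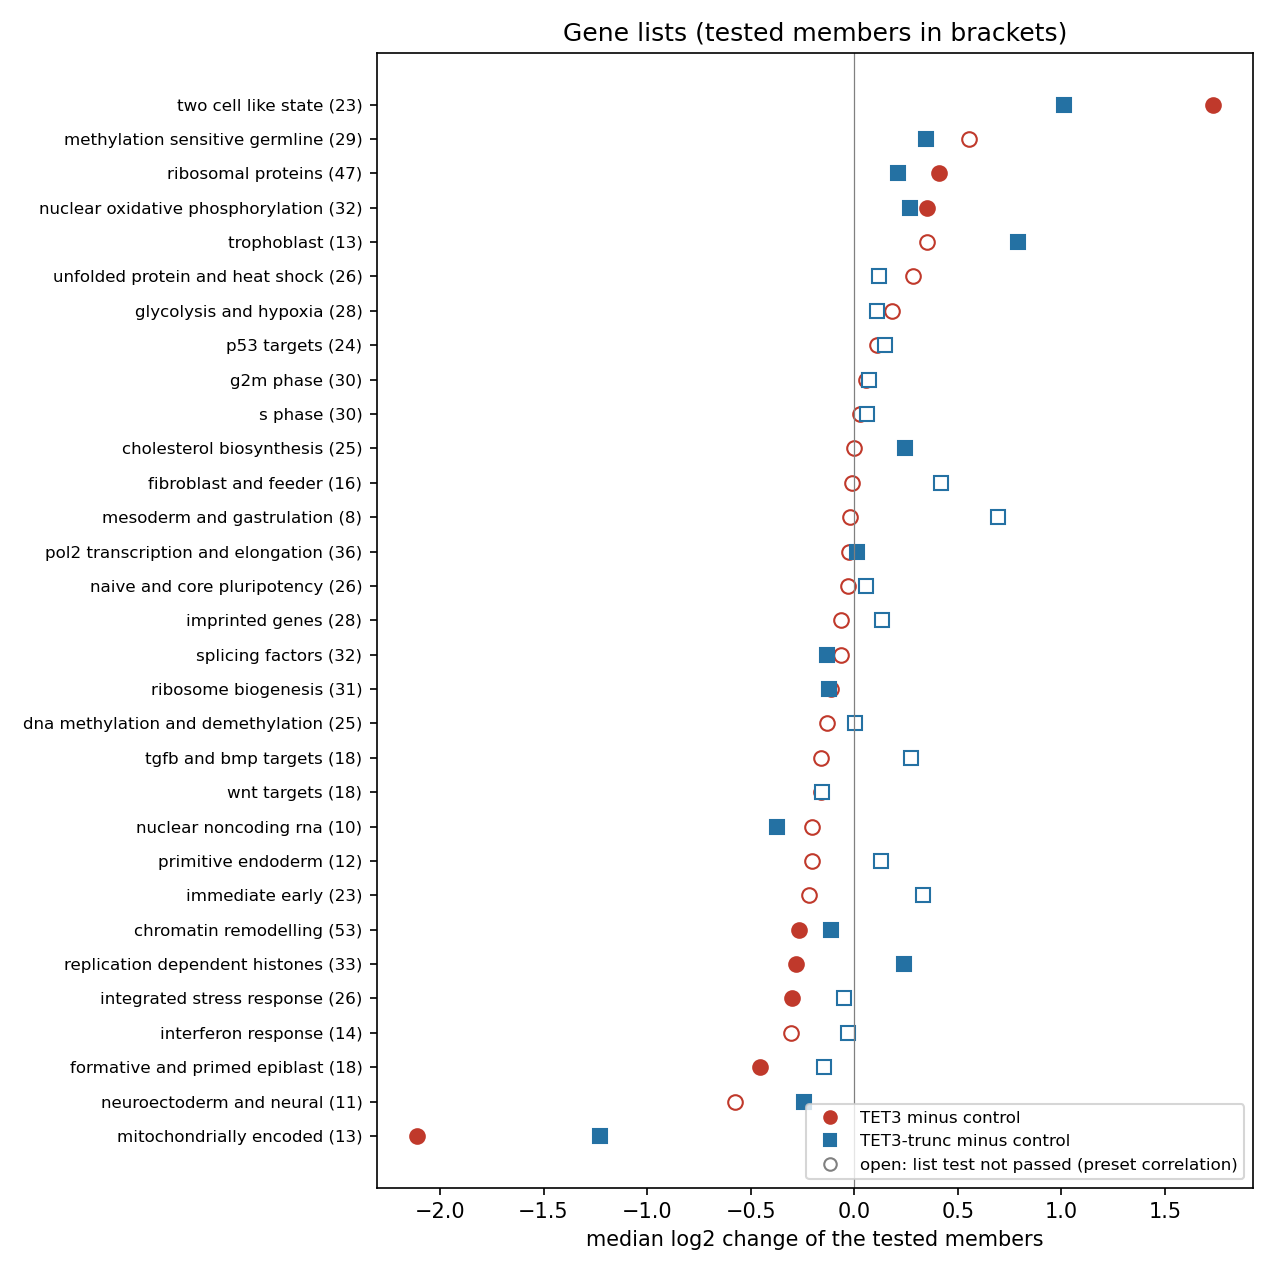
Median log2 change of the tested members of 31 gene lists, for TET3 minus control (circles) and TET3-trunc minus control (squares), with filled symbols where camera with the preset correlation gave an adjusted p under 0.05. The 2-cell-like list lies at 1.73 and 1.01 and the mitochondrial list at -2.11 and -1.23. With an estimated correlation 0 lists passed in either comparison.

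The third comparison set TET3 directly against TET3-trunc. No single gene passed, and 2769 genes had an unadjusted p below the threshold in limma. Voom also called 0 genes, but the count was 1642 without TET3 replicate 3. The histone list separated the constructs: 32 of 33 members were lower in TET3 than in TET3-trunc, 23 of them when adjusted over the list alone, with a median log2 change of -0.54. Camera gave adjusted p = 1.8e-12 for this list (adjusted p = 0.743 with an estimated correlation), and fry gave adjusted p = 0.0302, the only list of the 31 to pass fry in one direction in any of the 3 comparisons. Of single genes, Phlda2 was at 3.5 ± 2 RPM in TET3 and 12.8 ± 1.92 RPM in TET3-trunc, and Mest at 26.7 ± 8.14 and 56.1 ± 3.33 RPM, each with limma adjusted p = 0.0893. The 2-cell-like list was higher in TET3 by a median of 1.03 and the mitochondrial list had a median of -1.08. Tet3 reads differed by 1.95 on the log2 scale (limma adjusted p = 0.0893), and RPM does not correct for the length of the transcripts of the constructs.

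Of the 1186 genes other than Tet3 called in TET3, 1089 (91.8%) had the same direction in TET3-trunc. Genes higher in TET3 had a median log2 change of 0.39 in TET3-trunc and genes lower in TET3 a median of -0.19. Both effects share the 3 control libraries. Unchanged groups that share 3 libraries as control were simulated from the deviations of all 9 libraries. They gave 84.5% on average, and 18.2% to 100% between outer quantiles rather than extremes. The simulated intervals in brackets below are of the same kind. Across genes, which are not independent replicates, the 2 sets of log2 changes had r = 0.583, where the simulated mean was 0.462 (-0.197 to 0.894). Their covariance was 0.103, where the simulated mean was 0.0429 (-0.00938 to 0.123). The 3 controls cannot be split into 2 sets of at least 2 libraries. All 3 values lie inside the simulated intervals, so no effect common to the constructs is shown beyond what a shared control gives in this simulation. The control libraries themselves were not held fixed in it, so their own spread was not modelled. Only Tet3, the introduced gene, was called in both comparisons.

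The ATAC comparison asked whether chromatin is more accessible in TET3 cells. The tiles of highest mean ATAC signal held more of the reads in TET3. This share is relative to the other tiles of each library. Library quality was not tested, so the share alone does not show that chromatin is more accessible. Tiles in the top 1% by mean signal (10486 tiles of chromosomes 1, 2 and part of 3) took 5.69% ± 0.426 (SD, n = 3) of the summed RPM in TET3 and 3.94% ± 0.482 in control. The difference of 1.75 points had an exact two-sided permutation p of 0.1, the smallest that 3 libraries against 3 can give, and no TET3 library overlapped a control library. The 4683 tiles that hold a gene start took 1.89% ± 0.184 in TET3 and 1.33% ± 0.157 in control (exact permutation p = 0.1). Of 12 tested tiles at the starts of named genes, 7 had higher and 5 lower values in TET3. The largest of the differences were those of D1Pas1 and Tet2. At the start of the germline gene D1Pas1 (chromosome 1, 186967001 to 186967500) the ATAC signal was 1.71 ± 0.529 RPM in TET3 and 0.78 ± 0.194 RPM in control, and at the start of Tet2 it was 2.23 ± 0.842 and 1.08 ± 0.204 RPM. Neither tile passed the test (limma adjusted p = 0.563 and 0.622). At the start of Ncl, the gene of nucleolin, values were 2.42 ± 0.729 and 2.55 ± 0.75 RPM. At that of Ankrd34a they were 0.492 ± 0.375 and 0.578 ± 0.0953 RPM, and at that of Pmvk 0.765 ± 0.0416 and 0.912 ± 0.0924 RPM.

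**Figure D3:**
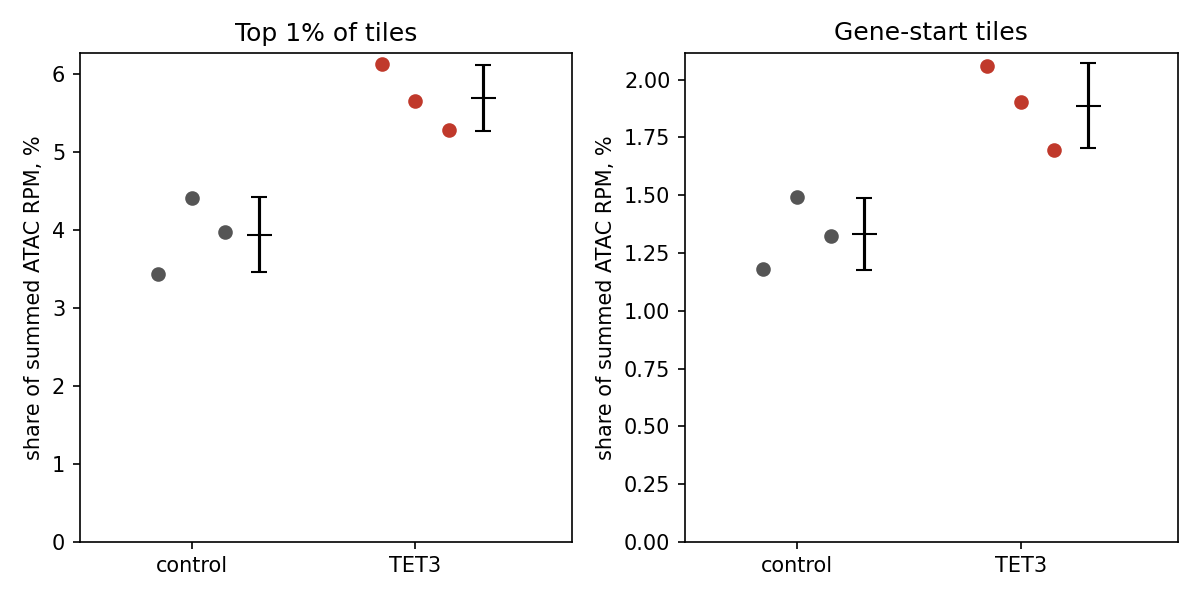
Share of the summed ATAC RPM, in percent, in the top 1% of tiles and in tiles that hold a gene start, for single libraries (points) with the mean ± SD of 3 libraries (black). TET3 libraries lie at 5.29% to 6.13% in the top tiles, above the control libraries at 3.44% to 4.4%.

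No single ATAC tile passed limma at the adjusted threshold among 30333 tested. An unadjusted p below the threshold was found for 1922 tiles, and the lowest adjusted p was 0.201. The libraries of the 2 groups did not overlap in 11.2% of tiles, where chance gives 10%. The count depended on the scaling: after a median shift of the libraries 194 tiles passed (178 higher and 16 lower), after quantile normalization 29 (15 higher and 14 lower), and with a filter at 1 RPM 35.

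The ChIP libraries asked where the constructs bind. The ChIP signal of all 3 constructs was enriched over the input at gene starts. The series holds no ChIP of control cells with this antibody. Signal that arises without a construct can therefore not be told apart from binding. Of the 1758 tested tiles that hold a gene start, 1253 were bound by TET3, 1191 by TET3-CXXC and 1261 by TET3-trunc. The tile at the shared start of Hspd1 and Hspe1, the paired genes of mitochondrial chaperonins (chromosome 1, 55088001 to 55088500), held 5.7 ± 1.32 RPM in TET3 (SD, n = 2), 5.29 ± 2.81 in TET3-CXXC and 7.04 ± 2.26 in TET3-trunc (n = 3 each), against 0.0369 RPM, or 1 read, in the input. At the start of Ncl (chromosome 1, 86359001 to 86359500) the values were 16.1 ± 1.37, 18.3 ± 10 and 20.7 ± 2.88 RPM against 0.443 RPM in the input. The tile at the start of Plcb4 (chromosome 2, 135659001 to 135659500) held 3.3, 4.09 and 4.24 RPM on average, with 0 reads in the input. At the start of D1Pas1 the means were 1.5 ± 0.17, 2.22 ± 1.34 and 2.49 ± 0.0651 RPM against 0.258 RPM. The highest enrichment shared by the constructs lay between genes, at 72244001 to 72244500 of chromosome 1, 31944 bp from the start of Mreg, with 69.2 ± 0.965 RPM in TET3, 81.6 ± 39.5 in TET3-CXXC and 88.6 ± 25.7 in TET3-trunc against 0.369 RPM in the input.

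In limma, 9483 of 105513 tiles differed between TET3 and input (9482 higher), 7404 between TET3-CXXC and input (7403 higher) and 12343 between TET3-trunc and input (all higher). Of these, 11.3%, 14.6% and 9.58% hold a gene start, against 1.67% of tested tiles. After a median shift, which removes the difference of 0.91, 0.14 and 0.80 in the median tested tile, 3264, 6157 and 4997 tiles passed. With no filter these medians were 0.0124, -0.598 and -0.0706, so the size of the shift rests on the filter. Quantile normalization gave splits of 6140 higher and 2228 lower, 7607 and 2087, and 7397 and 2315.

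By the rule on each library, 29537 tiles were bound by TET3, 11021 by TET3-CXXC and 22399 by TET3-trunc. Gene starts made up 4.24%, 10.8% and 5.63% of them. The rule asks each library to pass, and TET3 had 2 libraries where the others had 3. Its count, share and overlaps are therefore not on an equal footing with theirs. With each library left out, which leaves 2, TET3-trunc had 26385 to 30368 bound tiles and TET3-CXXC 11316 to 16056. The constructs shared 8400 bound tiles, where independent sets would share 655. TET3 and TET3-CXXC shared 9156 (3085 for independent sets), TET3 and TET3-trunc 14046 (6270), and TET3-CXXC and TET3-trunc 9583 (2340). All constructs were set against the same input, which adds to such overlaps. After a median shift of each library the counts were 9275, 9941 and 8687, with 5009 shared by all 3, so the larger number for TET3 and TET3-trunc is not kept.

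Direct comparisons of the constructs gave few tiles. TET3-CXXC differed from TET3 at 48 tiles, 44 of them lower. The lowest lay at 98667501 to 98668000 of chromosome 2, next to the tiles with the most reads in every ChIP library, the input included, with 0.199 ± 0.191 RPM in TET3-CXXC and 489 ± 60.8 in TET3. TET3-CXXC was lower than TET3-trunc at 75 tiles and higher at 0, among them the tile at the start of Phf21a, a chromatin reader gene (0.101 ± 0.0876 against 4.4 ± 0.577 RPM). Of these tiles, 74 could be matched to other tested tiles of the same TET3-CXXC level. Of the 74, 55.4% lay beside a tile of at least 8 times their own TET3-CXXC signal, against 0.918% of the matched tiles. TET3-trunc was higher than TET3 at 18 tiles, among them 1 within Uck2 (0.859 ± 0.157 against 0.0764 ± 0.108 RPM) and 1 within Elf5 (0.758 ± 0.465 against 0 RPM), and 592 tiles passed without TET3 replicate 1 and 0 without TET3-trunc replicate 1. The direction was not stable, with 2 higher and 3 lower without TET3-trunc replicate 2, 5 and 4 without TET3-trunc replicate 3, and 65 and 35 with no filter. For TET3-CXXC against TET3 the direction turned with the scaling, with 173 higher and 21 lower after a median shift and 67 higher and 26 lower after quantile normalization. It also turned when a library was left out, with 189 higher and 28 lower without TET3 replicate 1 and 36 higher and 20 lower without TET3 replicate 2.

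The last comparisons set binding beside accessibility and RNA. Tiles bound by TET3 were set against unbound tiles of like ATAC signal. Over 7638 bound tiles, of which 7550 could be matched, bound minus unbound was -0.02 ± 0.0219 log2 in TET3 and 0.03 ± 0.023 in control, a difference of -0.05 (exact permutation p = 0.1, n = 3), which was -0.000157 without ATAC TET3 replicate 1 and 0.19 without matching. The RNA change of genes with a bound start was set against that of unbound genes of like level (952 of 1103 bound genes matched, 287 unbound). The difference was -0.05 (exact permutation p = 0.5, n = 3), but -0.09 without RNA control replicate 2, -0.17 without matching and -0.1699 for any bound tile within 1 kb, each with exact permutation p = 0.1. Of the genes with a start tile in the table, TET3 bound the starts of 57 of 82 that rose (69.5%), 28 of 38 that fell (73.7%) and 1018 of 1270 that did not pass (80.2%). Ncl, bound by all constructs, fell from 696 ± 129 to 343 ± 33.9 RPM (limma adjusted p = 0.018), and D1Pas1, also bound, rose. Across 1921 genes, which are not independent replicates, RNA and start-tile ATAC changes had r = 0.0507 and rho = 0.056. The median ATAC change at gene starts was 0.37 on the log2 scale, 0.47 for 88 genes that rose in RNA and 0.29 for 66 that fell.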

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

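The tests of explanations in this part were chosen after the patterns had been seen, while the counts over other splits of the libraries were planned. In each paragraph on other splits, 3 libraries against 3 give 10 splits, which are too few for a share under 0.05.

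Between the TET3 and TET3-trunc effects, 6 gene lists differed, by the direct test of TET3 against TET3-trunc (camera with the preset correlation). The adjusted p was 5.86e-06 for the 2-cell-like list (median log2 difference 1.03), 3.91e-05 for mitochondrial transcripts (-1.08), 0.0277 for nuclear oxidative phosphorylation (0.12), 1.8e-12 for replication-dependent histones (-0.54), 0.0318 for the integrated stress response (-0.38) and 0.00307 for immediate early genes (-0.46). None held with an estimated correlation (adjusted p from 0.743 to 0.89), and fry passed for histones (adjusted p = 0.0302).

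The 2-cell-like genes were higher in TET3 than in control for all 23 members. Library depth as the whole explanation is argued against, since 12 members were still called after all libraries were thinned to the shallowest. Reads shared between family copies stay open, since only 1 of the 4 members outside multigene families was called. Variation between control cultures stays open as well: the lowest TET3 library lay 0.11 log2 above the highest control, less than the SD of 1.04 between controls. An effect of the TET3 construct itself is the biological explanation the design gives, and it cannot be told apart from this variation.

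Mitochondrial transcripts were lower in TET3 for all 13 members. After thinning 11 were still called, and under the median shift and quantile normalization at least 10, which argues against depth or scaling as the whole explanation. A smaller share of cytoplasmic RNA is argued against by 79 ribosomal protein and nuclear oxidative phosphorylation genes, whose median log2 change was 0.38 with an SD of 0.35. The library with most Tet3, TET3 replicate 3, had the smallest fall, and other differences between cultures were not tested. An effect of the construct is the biological explanation the design gives, and it stays open and untested.

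Of 74 tiles lower in TET3-CXXC than in TET3-trunc, 55.4% lay beside a tile of at least 8 times their TET3-CXXC signal, against 0.918% of other tested tiles of the same TET3-CXXC level. Reads that spread over a longer stretch in the TET3-trunc libraries would give this, and wider binding by TET3-trunc beside shared sites would look the same at these tiles. The table held 22.9% to 23.7% of the RPM of the TET3 and TET3-trunc libraries. For the TET3-CXXC and input libraries, the input being no binding sample, it held 15.5% to 16.3%. Whether this difference has the same origin was not tested. A constant difference in background level is argued against as the whole explanation for the 30 tiles that were still called under a median shift. For the set of 75 the median cannot decide, since the tiles were chosen for their low values. Under the median shift the median log2 change of the 75 called tiles went from -2.87 (SD 2.04) to -2.21 (SD 2.04), and 30 calls were kept. The 45 lost calls went from a median of -2.52 (SD 0.481) to -1.86 (SD 0.481) with a median standard error of 0.547 after the shift. Tiles with an unadjusted limma p below the threshold went from 12941 to 4560. Whether the smaller change or the adjustment over all tiles ended these calls was not tested.

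For TET3 against control, 1187 genes were called and the other splits called 0 at most, so 1 of the 10 splits, the real one, reached that count. For TET3-trunc against control the count was 1, with 0 at most in the others, and for TET3 against TET3-trunc it was 0, with 0 in the others. ATAC tiles gave 0 in the real split and 2 at most in another. Tiles of TET3-CXXC against TET3-trunc gave 75, with 7 at most in another.

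Gene lists behaved differently. The counts of lists given here use the preset correlation, and with an estimated correlation 0 lists passed in each comparison. For TET3 against control 8 lists passed with the preset correlation, and another split gave 12 (9 of the 10 splits gave at least 8). For TET3-trunc against control 14 passed and another split gave 20 (5 splits gave at least 14), and for TET3 against TET3-trunc 6 passed and another gave 17 (all 10 gave at least 6). In each comparison other splits thus passed as many lists, so these counts do not set the real grouping apart. Why other splits passed as many was not tested.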

How the results depend on the processing

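The array weights, thinned reads, pairs of libraries left out and the median shift of bound tiles were chosen after seeing the data, and the other alternatives were planned. Of 6696 values of single genes, tiles and lists under the alternatives, 5700 kept direction and side of the threshold, 739 lost the threshold and 196 passed it newly. A further 61 changed direction where neither fit passed the threshold, and 0 changed direction where either fit passed it. The setting of at least 1 log2 unit could not change such values, and its 348 values count among those kept. Named genes entered each RNA comparison, though no named gene but Tet3 was called outside TET3 against control. Many values kept thus had no call to lose. With each library left out, 368 of 1993 values lost the threshold. Of 103 values, 70 lost it without control replicate 2 and TET3-trunc replicate 1 together, and 85 without control replicate 3 and TET3-trunc replicate 1. The causes of the changes below were not tested, except where fewer libraries or features were used. With no filter, features without reads also enter, at the lowest value of each library, which differs with depth. Depth limits tiles with few reads, and the single input cannot be left out.

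RNA genes of TET3 against control (1187) numbered 9674 with no filter, 265 with voom on recovered reads, 562 with no trend, 520 at 1 log2 unit or more, 255 with only the 2 groups compared, 3839 with array weights, 98 without control replicate 2 and TET3-trunc replicate 1 together, and 13 without control replicate 3 and TET3-trunc replicate 1. Median shift and quantile normalization gave 1232 and 1363. With each library left out the count ran from 1 to 3143. TET3-trunc against control (1) gave 2 with log2(RPM + 1) and with quantile normalization, 7421 with no filter, 4 with no trend and 26 with array weights. TET3 against TET3-trunc (0) gave 82 with no filter, 4294 with array weights, and 0 to 1642 with each library left out. The correlation of the effects (0.583) was 0.766 with no filter and 0.464 to 0.726 with each library left out. With an estimated correlation 0 lists passed in each comparison.

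ATAC tiles (0) numbered 35 with a filter at 1 RPM, 194 with the median shift, 29 with quantile normalization, and 0 to 12 with each library left out. The share in the most accessible tiles differed by 2.38 points for the top 5% and 0.907 for the top 0.2%. Against input (9483, 7404 and 12343 for TET3, TET3-CXXC and TET3-trunc), log2(RPM + 0.5) gave 4280, 3326 and 7466. No filter gave 22348 for TET3, of which 7945 were higher and 14403 lower, and the median shift gave 3264 for TET3 and 4997 for TET3-trunc. TET3-CXXC against TET3 (48) gave 16005 with no filter (14353 higher and 1652 lower), 23 with the filter at 1 RPM, 194 with the median shift and 93 with quantile normalization, and 26 to 217 with each library left out. TET3-trunc against TET3 (18) gave 0 with log2(RPM + 0.5), 100 with no filter (65 higher and 35 lower), 8 with the filter at 1 RPM, 32 with the median shift, 30 with quantile normalization, and 0 to 592 with each library left out. TET3-CXXC against TET3-trunc (75) gave 44 with log2(RPM + 0.5), 32 with the median shift, 33 with quantile normalization, and 35 to 134 with each library left out.

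Bound tiles of TET3, TET3-CXXC and TET3-trunc numbered 10365, 4128 and 8665 at 2 log2 units, with 3386 shared. With the mean of the libraries TET3-trunc had 33830 and 12993 were shared. After a median shift TET3 had 9275 and TET3-trunc 8687, with 5009 shared. With each library left out, TET3 had 40819 to 42610, TET3-CXXC 11316 to 16056 and TET3-trunc 26385 to 30368. The ATAC change at bound tiles (-0.04518) was 0.19 with no matching, -0.06978 for tiles bound by TET3-CXXC, -0.02059 with log2(RPM + 0.5), and from -0.05094 to -0.000157 with each library left out. The RNA change at bound promoters (-0.04569) was -0.1701 with no matching and -0.1699 for any tile within 1 kb.

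Deviations of replicates with the same number had correlations of mixed sign, from -0.539 to 0.526 in RNA (0.0617 to 0.318 between TET3 and control) and from -0.0329 to 0.0645 in tiles, so the numbers were not taken as pairs. With the replicate number as a block, RNA calls were 1248, 1 and 0, lists 9, 15 and 8, ATAC tiles 0, and tiles of TET3-CXXC against TET3, TET3-trunc against TET3 and TET3-CXXC against TET3-trunc 54, 11 and 68.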

Other observations

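The tests of explanations in this part were chosen after the results had been seen.

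Several metabolic genes changed in TET3. Of 25 genes of cholesterol synthesis Ebp (2.31-fold), Mvk (1.89-fold) and Pmvk (1.85-fold) rose, and 4 were higher when adjusted over the list alone. Of 28 genes of glycolysis and hypoxia the phosphofructokinases Pfkp (1.8-fold) and Pfkl (1.62-fold) rose, Gapdh fell to 0.595 of its control level (limma adjusted p = 0.0398) and Ero1l fell too, with 5 higher and 3 lower when adjusted over the list alone. Neither list passed camera (adjusted p = 0.421 and 0.426). Of 26 genes of the unfolded protein and heat shock response Creld2 (2.06-fold) and Sdf2l1 (1.78-fold) rose and the chaperone Hsp90aa1 fell, with 2 higher and 1 lower when adjusted over the list alone (camera adjusted p = 0.0895).

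Signalling and cell cycle genes changed in small numbers. The Wnt-pathway factors Tcf7l1, Tcf7l2 and Tcf7 fell among 18 Wnt genes, and 6 were lower when adjusted over the list alone (camera adjusted p = 0.0684). Tgif1, a repressor of TGF-beta responses, fell from 63.2 ± 11.2 to 35.4 ± 14.3 RPM. Among p53-related genes Sesn1 rose 2.05-fold and Trp53 itself fell from 142 ± 21.6 to 76.1 ± 38.4 RPM (limma adjusted p = 0.0473). Cdc45 and Cdk1 rose and Ube2c fell, while the S phase and G2/M lists had medians of 0.03 and 0.06. The splicing factors Rbm25 and Srsf11 fell, and the interferon gene Oas1a rose by 0.97 on the log2 scale.

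The hypothesis that TET3 binding sets where accessibility differs was tested at bound tiles against matched unbound tiles. The difference between TET3 and control was -0.04518 on the log2 scale, where the SD between libraries was 0.0225, but it was -0.000157 without ATAC TET3 replicate 1, so no direction could be given. The hypothesis that ATAC signal at gene starts follows RNA was tested as the median ATAC change of genes that rose minus that of genes that fell. It was 0.18 (bootstrap standard error over genes 0.0819), and per library the difference was 0.20 with overlapping groups (exact permutation p = 0.3, n = 3), so this too stays undecided.

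The 2 tiles with the most ATAC reads, chosen after their values were seen, differed in opposite directions. The first, at 24613001 to 24613500 of chromosome 1, held 302 ± 111 RPM in TET3 (211 to 426) and 129 ± 61.9 RPM in control (68.5 to 192), with an exact two-sided permutation p of 0.1 (n = 3). The second, at 98667001 to 98667500 of chromosome 2, held 96.9 ± 7.42 RPM in TET3 (88.4 to 102) and 132 ± 15.3 RPM in control (115 to 145), with the same exact p of 0.1. That tile of chromosome 2 also held the most reads in the ChIP input, 4.159% of those in the ChIP table. Its high signal is thus not particular to ATAC. Whether the reads of either tile reflect accessible chromatin was not tested, so these differences are not given as changes in accessibility.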
